A study of Drosophila melanogaster with 33 samples.

How the data were processed

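Total RNA from Drosophila larval brains and from cultured tumours had been hybridised to Affymetrix Drosophila arrays, 1 array per sample. Per the labels, the deposited values are log2 expression values made by the authors with GCRMA, a method that corrects background with the probe sequence, normalises between arrays and gives 1 value per probe set. Its version and settings were not stated. The values ran over 18952 probe sets on 33 arrays, and 183 control probe sets were left out of the tests. Arrays have no read depth, so the number of arrays per group, 3 or 6, limits the precision.

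The samples fell into 9 groups by allele, temperature and culture round, as the sample titles give them, and into 2 experimentation sites, IRB with 24 arrays and EMBL with 9. Wild type (WT) and the ts1 homozygotes at 29 °C had arrays at both sites, and every other group had arrays at 1 site. Per the deposited values, the WT mean at IRB equalled the WT mean at EMBL for all 18952 probe sets, with a largest difference of 6.7e-09. In the ts1 brains at 29 °C the same difference reached 7.2, with a median of 0.319. The sites had therefore been centred on WT before deposition, and the labels do not describe that step. A site term fitted with WT and ts1 brains together takes in part of the site difference of the ts1 brains themselves. For this reason values within a site are given in the results where a call named there was lost or a named difference moved by over 1.5 times. Within IRB or within EMBL means a fit of the arrays of that site alone, unless a fit of all arrays is named.

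Each gene was represented by 1 probe set, the one with the highest mean over all arrays among the 13647 probe sets annotated to that gene alone. Another 402 probe sets named several genes and 4720 were not listed in the annotation, so neither kind was used for a named gene. Of 11982 genes, the 8264 with a log2 value over 4 on at least 3 arrays were tested. The low-value filter, the test, the comparisons, the gene lists and the first set of alternatives were fixed before the data were examined.

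Differences were tested in R 4.3.3 with limma 3.58.1, in 1 linear model with the 9 groups and a site term, followed by empirical Bayes moderation, and p was adjusted by Benjamini-Hochberg over the 8264 genes. A gene was called at an adjusted p under 0.05 and an absolute log2 difference of at least 1, a 2-fold change. Differences are given with their standard error (SE) from this model, and group means with their standard deviation (SD) over arrays. Where a group averaged below 4, its signal is near background, and the size of a difference from it is not exact. The p-values measure only the spread between these samples, and the labels do not say whether the arrays hold separate pools of animals. The WT means are equal at both sites by the centring, so the SD of WT holds no spread between sites. The SD of the ts1 brains with arrays at both sites keeps that spread. The residual spread of WT in the model lacks it too, so SEs and p-values against WT can be too small. Replicate numbers were checked for pairing: in none of the pairs of groups did every pair of same-numbered arrays correlate above 0.1, so the numbers were not used as pairs.

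The comparisons set each mutant and tumour group against WT, 29 °C against 17 °C within each allele, the temperature effect of ts1 against that of E2, round-1 tumours against ts1 brains at 29 °C, and round-10 against round-1 tumours. Genes called in the same direction in all 6 comparisons of 29 °C brains and tumours with WT were counted.

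The 25 gene lists covered the piRNA pathway, germline stem cell and oogenesis genes, meiosis genes, testis genes, chorion and vitelline membrane genes, yolk proteins and adult fat body, larval fat body, muscle, hemocytes, tracheal and cuticle genes, antimicrobial peptides and immune response, neuroblast and ganglion mother cell genes, neuronal genes, glial genes, optic lobe neuroepithelium and lamina genes, eye and other imaginal disc genes, Hippo pathway targets and members, cell cycle and DNA replication genes, l(3)mbt complexes (dREAM and LINT), heat shock proteins, JNK and JAK-STAT signalling genes, glycolysis, oxidative phosphorylation, sex composition, and ecdysone response and metamorphosis genes. Lists of 5 or more tested genes were tested with limma's camera at a preset correlation of 0.01, which compares a list with all other genes, and again with an estimated correlation. Camera p-values were adjusted over the lists within a comparison.

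The genes named in the text follow a rule. It takes l(3)mbt everywhere, then the called genes with the largest differences whose group arrays do not overlap and whose higher group mean exceeds 4. It takes 10 each way in the comparisons of 29 °C brains with WT, of temperatures within an allele and of tumours with brains or with each other, and 3 each way elsewhere. It adds 15 shared genes each way and up to 4 called genes per list and comparison. Genes with only a CG number were mostly left out.

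Alternatives changed the site term, the sites used, the low-value filter, the groups in the fit, the probe sets per gene, the normalisation, the variance model, array weights, the fold minimum, the replicate block and the camera correlation, and left out each array in turn. After the data were seen, 4 further alternatives were added: a site term from WT alone, the fit without 3 arrays with weak 5' control signal, the fit without 5 arrays that stand apart, and the last of these with the site term from WT alone. Self-tests on simulated data added differences to 100 genes per comparison. At a difference of 1.5 they recovered between 44 and 71 of 100, at a difference of 3 between 82 and 93 of 100, and between 1 and 9 unchanged genes were called. The simulated noise was independent between genes and arrays. These numbers therefore do not cover arrays that stand apart or genes that vary together. The median difference over all genes was -0.17 for E2 brains at 29 °C against WT and -0.13 for E2 brains at 29 °C against 17 °C. It was 0.12 for round-5 and 0.11 for round-10 tumours against WT.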

Results

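Expression was measured on 33 Drosophila arrays, 1 per sample, of larval brains mutant for l(3)mbt, of tumours grown from them and of wild-type brains. The gene l(3)mbt encodes a chromatin protein with malignant brain tumour repeats, and its loss lets the larval brain overgrow. The allele ts1 is temperature sensitive and was assayed at 17 °C (3 arrays) and at 29 °C (6 arrays). The allele E2 was assayed at 17 °C and 29 °C, and the ts1/E2 transheterozygote at 29 °C, with 3 arrays each. Tumours of ts1 brains kept by serial transplantation into adult flies were sampled at round 1, round 5 and round 10, with 3 arrays each. Wild type (WT, w1118) had 6 arrays. No WT array was assigned to a temperature, so comparisons with WT cannot part the allele from the temperature. The first principal component took up 44.4% of the variance and placed WT at 55.7 to 61.1 and the tumours at -117.3 to -86.4, with E2 at 17 °C replicate 2 the highest at 65.8.

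Signal from the 5' end of control transcripts was weak on 3 arrays. For eIF4a, the 5' probe set minus the 3' probe set was -11.96 on E2 29 °C replicate 1, -5.25 on ts1 17 °C replicate 2 and -4.94 on ts1 29 °C replicate 3, against -2.38 or higher on the other 30 arrays. E2 29 °C replicate 1 also had the lowest second component, at -170.7, and a median correlation with its own group of 0.741. ts1 29 °C replicate 6 (-90.9) and E2 17 °C replicate 2 (-56.8) followed on the second component, and replicate 6 had a median correlation of 0.81 with its group. These 2 and the 3 with weak 5' signal are the 5 arrays that stand apart.

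**Figure D1:**
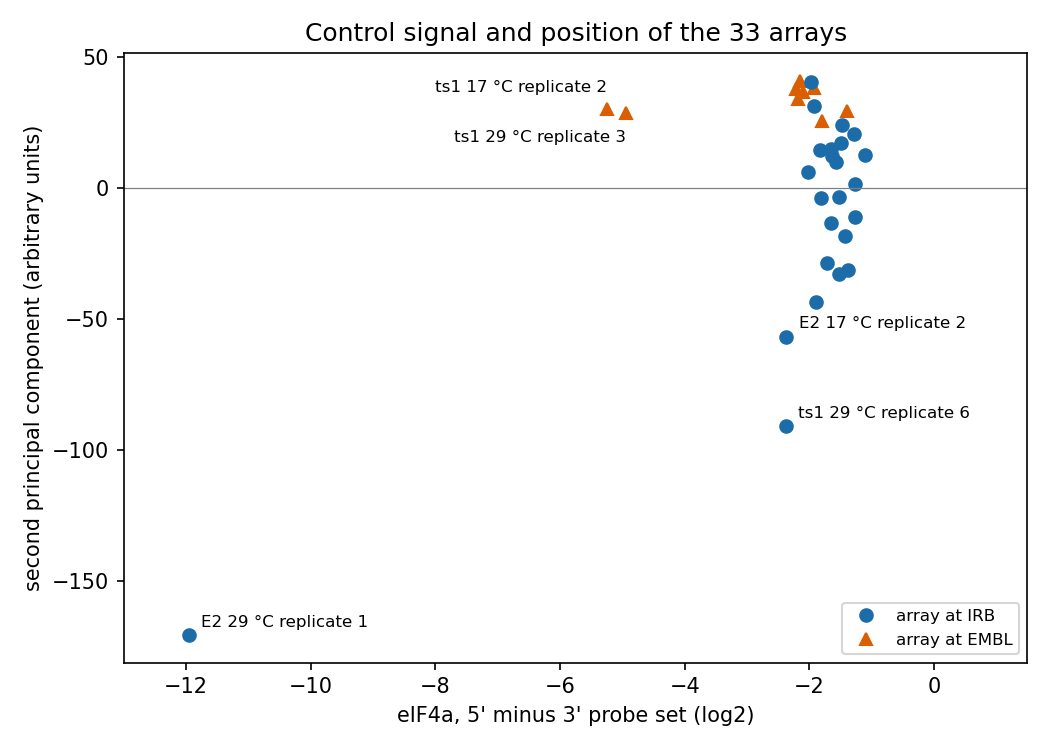
Second principal component (arbitrary units) against the eIF4a 5' minus 3' signal (log2), 1 point per array, circles for IRB and triangles for EMBL. E2 29 °C replicate 1 lay at -11.96 and -170.7, apart from the other arrays.

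The first question was what ts1 brains express at the restrictive temperature. Compared with WT, ts1 brains at 29 °C carried high levels of several germline transcripts. The gene cona, which encodes a synaptonemal complex protein of meiosis, rose from 2.90 ± 0.16 (SD, n = 6) in WT to 12.05 ± 0.51 (SD, n = 6), adjusted p = 5.74e-23 (limma, Benjamini-Hochberg). Pxt, a peroxidase required in oogenesis, rose by 9.33 ± 0.47 (SE), and Kots by 9.02 ± 0.28. krimp, a Tudor-domain protein of the piRNA pathway, which silences transposons in the germ line, rose from 2.73 ± 0.21 to 9.74 ± 0.70. The thioredoxin gene dhd of the female germ line rose by 6.35 ± 0.41, the zinc transporter gene Zip102B by 7.54 ± 0.21 and the mucin gene Muc14A by 5.48 ± 0.25. Tektin-C, which encodes a microtubule protein of sperm tails, fell by 8.25 ± 0.81, from 10.43 ± 0.03 in WT. Within IRB and within EMBL the differences were 10.58 and 8.07 for Pxt, 9.90 and 8.15 for Kots, 8.28 and 6.80 for Zip102B, and -9.40 and -7.10 for Tektin-C.

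In all, limma called 540 of 8264 genes in ts1 brains at 29 °C against WT, of which 322 were lower and the others higher. Of 28 piRNA pathway genes, 15 rose, 0 fell and 13 were not called, and 15 rose when adjusted over the list alone. Among them were the Argonaute gene AGO3, higher by 4.39 ± 0.50, the Tudor-domain gene tej, by 4.35 ± 0.43, and fs(1)Yb, by 3.67 ± 0.61. The camera test of this list gave an adjusted p of 6.91e-16, and adjusted p = 0.0403 with an estimated correlation. Of 27 germline stem cell and oogenesis genes, 9 rose (11 adjusted over the list alone), including bam, which drives germ cell differentiation, by 4.19 ± 0.69 and the gap junction gene zpg by 3.19 ± 0.65. Within IRB the calls of fs(1)Yb, bam and zpg were lost, with adjusted p of 0.136, 0.0638 and 0.429. Within IRB and within EMBL AGO3 differed by 2.87 and 5.91, tej by 3.39 and 5.31, corolla by 4.24 and 5.66, fs(1)Yb by 2.22 and 5.12, bam by 3.45 and 4.94 and zpg by 1.13 and 5.26. Camera gave an adjusted p of 8.08e-06 for the germline list, and adjusted p = 0.00187 with an estimated correlation. Of 19 meiosis genes, 5 rose (5 adjusted over the list alone), among them corolla by 4.95 ± 0.54 and sunn by 4.19 ± 0.46. Camera gave an adjusted p of 0.00035 for this list and adjusted p = 0.134 with an estimated correlation. Of 21 testis genes, 3 rose and 2 fell (5 and 2 adjusted over the list alone), the mean difference being 0.55. The transcription factor gene topi of spermatocytes rose by 2.83 ± 0.54, and the camera result of 0.000477 became adjusted p = 0.153 with an estimated correlation.

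Some glial, neuronal and optic lobe genes fell in ts1 brains at 29 °C. Of 23 glial genes, 3 fell and 20 were not called (5 fell adjusted over the list alone): gcm2, a glial cell fate factor, fell by 2.62 ± 0.38, naz by 2.19 ± 0.70 and repo, the general glial transcription factor, by 1.04 ± 0.27. The call of naz was lost within IRB and within EMBL (adjusted p = 0.0634 and 0.429), and it stood at -1.29 without the 5 arrays that stand apart (adjusted p = 0.0579). The repo call was lost within IRB, at -0.74 (adjusted p = 0.289). Camera placed the list lower, with an adjusted p of 0.00035 and adjusted p = 0.0403 with an estimated correlation. Of 23 neuronal genes, 4 fell, both over all genes and adjusted over the list alone, among them the synaptic genes nSyb by 1.25 ± 0.29 and Syn by 1.15 ± 0.30. Both calls were lost within IRB, at -0.88 and -1.26 (adjusted p = 0.141 and 0.104), and within EMBL, at -1.63 and -1.03 (adjusted p = 0.0732 and 0.0744). The camera result of 0.00179 became adjusted p = 0.397 with an estimated correlation. Of 16 optic lobe genes, 4 fell, also adjusted over the list alone, led by gl, a photoreceptor factor, by 2.40 ± 0.68 and followed by dac (adjusted p = 0.000541). The gl call was lost within EMBL (adjusted p = 0.279) and the dac call within IRB, at -1.74 (adjusted p = 0.103). Camera gave 0.0327, and adjusted p = 0.134 with an estimated correlation. Larval fat body genes were lower too, with all 3 tested called: Fbp1 fell by 5.46 ± 0.85 and the storage protein gene Lsp2 by 3.79 ± 1.12 (3 adjusted over the list alone). Fbp1 averaged 9.77 ± 1.53 (SD) in WT, and whether fat body tissue contributed to the brain samples was not tested. Within EMBL the calls of Fbp1 and Lsp2 were lost, with adjusted p of 0.161 and 0.591. Within IRB and within EMBL Fbp1 differed by -6.64 and -4.28, Lsp2 by -5.53 and -2.06, naz by -3.03 and -1.35 and gl by -3.59 and -1.21. In the Hippo growth pathway, 2 of 14 genes rose, crb by 1.46 ± 0.31 and ex by 1.19 ± 0.23, 2 also adjusted over the list alone, and camera gave an adjusted p of 0.0696. The crb call was lost within IRB, at a difference of 1.55 (adjusted p = 0.0647). The transcript of l(3)mbt itself stood at 7.91 ± 1.18 against 7.52 ± 0.35 in WT, adjusted p = 0.596.

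The ts1 brains at 29 °C differed between the experimentation sites. limma called 1566 genes between the 3 IRB and the 3 EMBL arrays, 539 higher and 1027 lower at IRB, while in WT, centred by site before deposition, it called 0, with 0 genes at an unadjusted p under 0.05. Set against the WT difference, which is 0 by that centring but adds the error of the WT arrays, 304 genes were called, 90 higher and 214 lower at IRB. The germline genes piwi, nanos, bgcn and c(3)G, chosen after their values were seen, were lower at IRB: piwi by -6.19 ± 0.33 (SE), nanos by -4.67 ± 0.49, bgcn by -3.90 ± 0.50 and c(3)G by -3.33 ± 0.49. krimp differed by 0.00 ± 0.32 and cona by 0.18 ± 0.26. In that fit of all arrays, with WT and ts1 brains parted by site, 305 genes were higher than WT at EMBL, 257 at IRB and 70 at both. Of those lower, the numbers were 254, 469 and 45, and 6 genes were higher at one site and lower at the other. Across genes, which are not independent replicates, the differences from WT at both sites had a Pearson r of 0.293. Fits of the arrays of 1 site alone called 418 genes higher and 243 lower within EMBL, and 152 higher and 356 lower within IRB. In these, the piRNA list had 19 genes higher than WT within EMBL and 4 within IRB, the germline list 10 and 0, the neuronal list 4 and 0 genes lower. Within EMBL l(3)mbt was higher than WT by 1.06 (adjusted p = 0.0157), and within IRB the difference was -0.29 (adjusted p = 0.838).

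**Figure D2:**
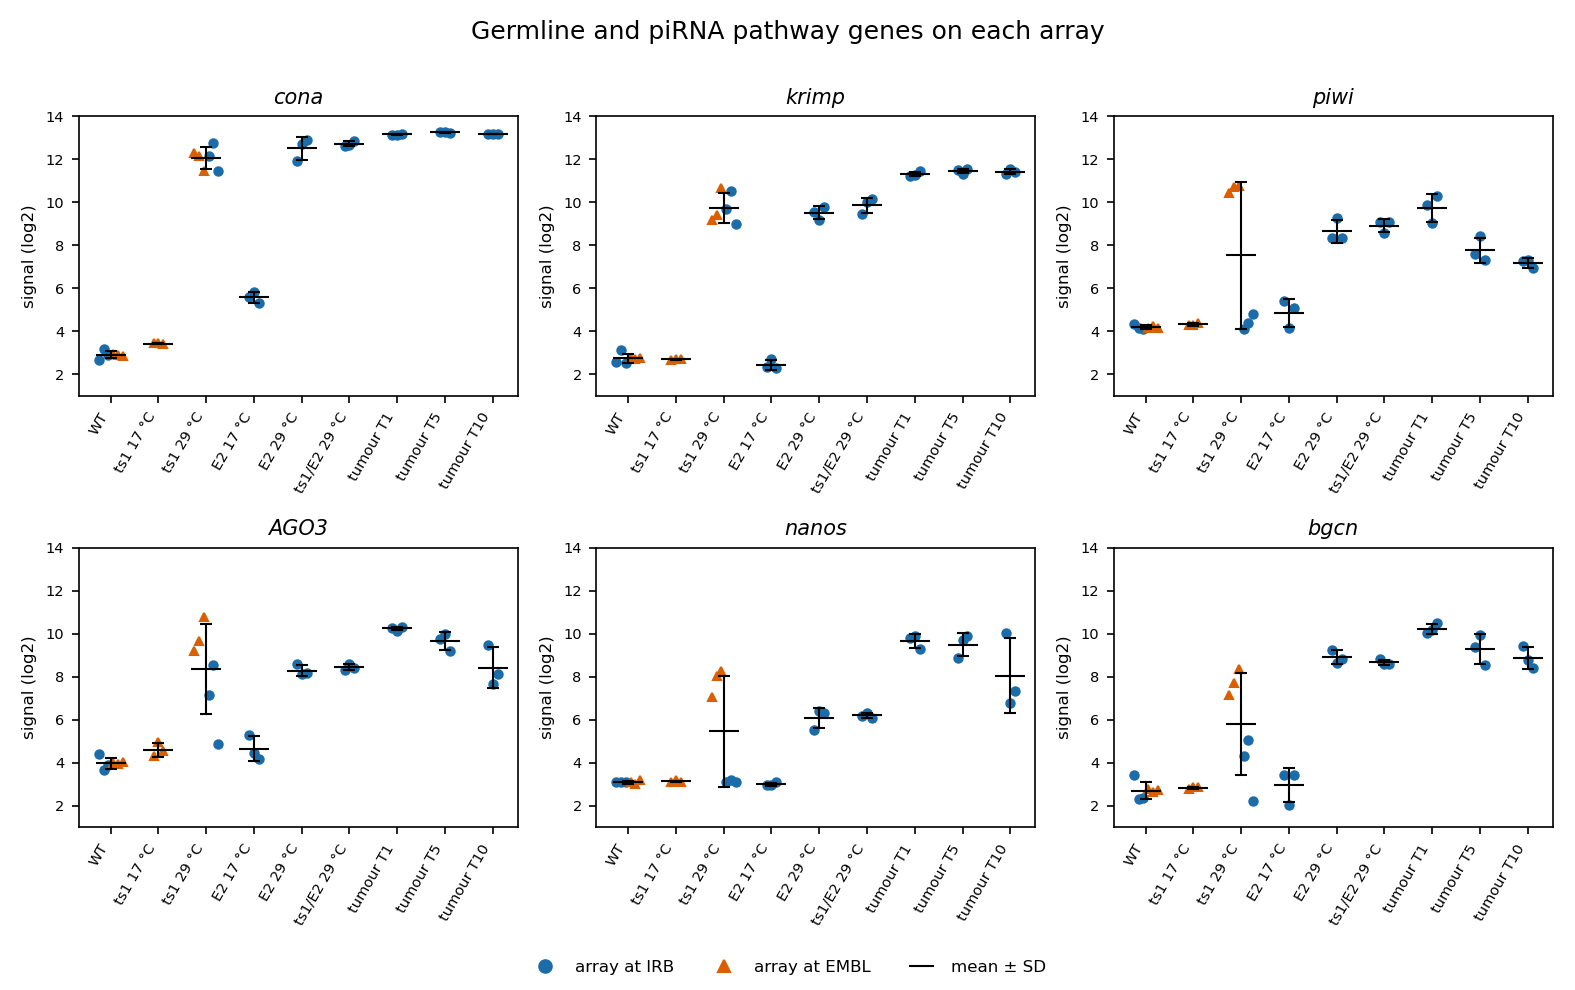
Log2 expression of germline genes on each array by group, with points for arrays and lines for group means. krimp averaged 2.73 in WT and 9.74 in ts1 brains at 29 °C, while piwi split in that group by site.

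The E2 brains asked whether another allele gives the same profile. At 29 °C they also carried high levels of several germline transcripts. cona rose from 2.90 ± 0.16 (SD, n = 6) in WT to 12.51 ± 0.54 (SD, n = 3), a fitted difference of 9.57 ± 0.24 (SE), adjusted p = 2.04e-20 (limma, Benjamini-Hochberg). Muc14A rose by 9.14 ± 0.34, Pxt by 9.02 ± 0.62, and TrxT, the testis paralog of dhd, by 7.90 ± 0.93. krimp rose by 6.77 ± 0.29 and bgcn, which acts with bam in germ cell differentiation, by 7.18 ± 0.69. piwi, the founding Argonaute of the pathway, averaged 8.64 ± 0.53 against 4.19 ± 0.08 in WT. Its fitted difference was 6.0 ± 0.87, and within the IRB arrays 4.45. Within IRB the differences were 9.65 for Pxt, 7.16 for TrxT and 6.20 for bgcn.

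limma called 817 genes, 355 higher and 462 lower in E2 brains at 29 °C than in WT. Of 28 piRNA genes, 12 rose and 1 fell (17 and 2 adjusted over the list alone), with a camera result of 1.17e-11 and adjusted p = 0.127 with an estimated correlation. Of 27 germline genes, 10 rose (12 adjusted over the list alone), among them stil, which is needed in the female germ line, by 6.41 ± 0.59 and zpg by 4.80 ± 0.86. Camera gave 3.01e-06, and adjusted p = 0.00119 with an estimated correlation. Of 19 meiosis genes, 5 rose and 2 fell (the same counts adjusted over the list alone), corolla by 6.01 ± 0.72 and vilya by 3.87 ± 0.74 being higher. Camera gave 0.00475, and adjusted p = 0.371 with an estimated correlation. Of 21 testis genes, 4 rose and 2 fell (the same counts adjusted over the list alone), topi by 4.43 ± 0.71 and ocn by 3.93 ± 0.52 being higher. Camera gave 0.00126, and adjusted p = 0.348 with an estimated correlation. Tektin-C fell by 8.82 ± 1.07, Fbp1 by 6.40 ± 1.13, the odorant-binding protein gene Obp99b by 5.71 ± 1.38 and the immunoglobulin-domain gene dpr5 by 4.82 ± 0.38. The neural stem cell factor tll fell by 1.81 ± 0.49, and differed by -1.33 without the 5 arrays that stand apart, where it was not called (adjusted p = 0.0558). The apical polarity gene crb rose by 2.63 ± 0.41. Within IRB zpg differed by 3.76, vilya by 3.20, Fbp1 by -6.99 and Obp99b by -7.08. l(3)mbt differed by 0.54 ± 0.52, adjusted p = 0.49.

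Over the 462 genes called lower in E2 brains at 29 °C, replicate 1, the array with the weakest 5' control signal, lay below the other E2 arrays by a median of -2.28, against -0.08 for the 355 genes called higher. Within the IRB arrays 485 genes were called, 250 higher and 235 lower, and without replicate 1 limma called 387, 95 of them lower. Tektin-C averaged 1.03 ± 0.02 (SD, n = 3) in the group, Fbp1 2.79 ± 0.05 and dpr5 0.73 ± 0.01, so these were low on all 3 arrays. Tektin-C and dpr5 lay below the lower quartile of the probe sets on these arrays, 2.25 to 2.31, and Fbp1 was near background too. The sizes of these falls are therefore not exact, and SDs at background do not measure agreement between brains. The calls of the neuroblast factor dpn, the cell cycle genes E2f2 and Dp, the respiratory chain gene ND-75 and the citrate transporter gene Indy, with adjusted p between 0.0138 and 0.0486 in the fit of all arrays, were lost within IRB, where adjusted p lay between 0.0573 and 0.117. The differences within IRB, which keeps replicate 1, were -1.32 for dpn, -1.72 for E2f2, -0.98 for Dp, -2.46 for ND-75 and -1.20 for Indy. They were -1.58, -1.64, -1.01, -2.34 and -1.38 in the fit of all arrays. Without the 5 arrays that stand apart they were -1.17, -0.72, -0.29, -0.74 and -0.72, and none was called.

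The transheterozygote ts1/E2 at 29 °C asked whether both alleles act on the same gene. It resembled the homozygotes in its highest genes. cona rose to 12.73 ± 0.12 (SD, n = 3), by 9.78 ± 0.24 (SE) over WT, adjusted p = 1.18e-20 (limma, Benjamini-Hochberg). Pxt rose by 9.35 ± 0.62, gnu, a regulator of the embryonic cell cycle, by 7.93 ± 1.13, and stil by 7.56 ± 0.59. krimp rose by 7.13 ± 0.29, and piwi by 6.26 ± 0.87, with 4.71 within IRB. Tektin-C fell by 8.82 ± 1.07 and the chitinase gene Cht5 by 4.95 ± 0.87. The ecdysone response factor Sox14 fell by 5.41 ± 1.02. Within IRB Pxt differed by 9.98, gnu by 7.24 and Cht5 by -4.32.

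limma called 523 genes in ts1/E2 brains, 321 higher and 202 lower than in WT, and 401 within IRB, 244 higher and 157 lower. The piRNA list had 13 of 28 genes higher (17 adjusted over the list alone), with a camera result of 4.34e-14 and adjusted p = 0.0445 with an estimated correlation. In the germline list 8 of 27 genes rose (8 adjusted over the list alone), with a camera result of 1.73e-05 and adjusted p = 0.00269 with an estimated correlation. Of 19 meiosis genes, 5 rose and 1 fell (the same counts adjusted over the list alone), with 0.0121 and adjusted p = 0.54 with an estimated correlation. Among 25 neuroblast genes, 4 fell, also adjusted over the list alone, tll by 2.06 ± 0.49, dpn by 1.71 ± 0.41, ase by 1.26 ± 0.26 and mira by 1.17 ± 0.30. Camera gave 0.0478 for this list, and adjusted p = 0.678 with an estimated correlation, and within IRB 2 of the genes fell, the calls of dpn and mira being lost at -1.46 and -1.21 (adjusted p = 0.0624 and 0.0588). The optic lobe list was lower at 0.0066, and adjusted p = 0.0445 with an estimated correlation, with 1 of 16 genes falling (1 adjusted over the list alone). l(3)mbt differed by 0.90 ± 0.52, adjusted p = 0.355.

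At 17 °C, the permissive temperature of ts1, cona and krimp stayed low in ts1 brains, while Kots and Pxt averaged above WT. In these brains, cona stood at 3.42 ± 0.03 (SD, n = 3) and krimp at 2.69 ± 0.02. Kots stood at 5.26 ± 0.61 against 2.34 ± 0.08 in WT, and Pxt at 4.95 ± 1.07 against 2.41 ± 0.11. limma called 57 genes against WT, 28 higher and 29 lower. Zip102B rose by 6.90 ± 0.28 (SE), adjusted p = 3.34e-15, st, an eye pigment transporter gene, by 5.31 ± 1.21, and the activin gene Actbeta by 4.84 ± 0.46. Tektin-C fell by 7.67 ± 1.07, Fbp1 by 7.07 ± 1.13 and Obp99b by 6.99 ± 1.38. The calls of Fbp1 and Obp99b were lost within EMBL, where the differences were -6.48 and -5.62 and adjusted p was 0.188 and 0.197. Without the 5 arrays that stand apart Obp99b differed by -5.49 (adjusted p = 0.0626), and with a site term from WT alone st differed by 5.10 (adjusted p = 0.0509). No piRNA gene was called by limma over all genes, and 2 of 28 rose adjusted over the list alone, with a camera adjusted p of 0.359. This depended on the site term. With a site term from WT alone 3 piRNA genes were called higher, and camera placed the list higher at an adjusted p of 0.00407. Within EMBL 1 was called higher. Over all tests of this comparison, 675 genes had an unadjusted p under 0.05. The neuronal list was lower, with 2 of 23 genes falling adjusted over the list alone. Camera gave 0.000532, and adjusted p = 0.862 with an estimated correlation. l(3)mbt differed by 0.43 ± 0.52, adjusted p = 1.

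In E2 brains at 17 °C, 221 genes were called, 137 higher and 84 lower than in WT. The noncoding RNA gene lncRNA:CR32368 rose by 8.85 ± 0.51 (SE), adjusted p = 5.65e-12 (limma, Benjamini-Hochberg), Zip102B by 8.12 ± 0.28 and the drosomycin-like gene Drsl5 by 6.80 ± 0.91. cona rose by 2.63 ± 0.24, to 5.57 ± 0.25 (SD, n = 3), and betaTub85D, the testis tubulin gene, by 2.68 ± 0.59. Tektin-C fell by 8.81 ± 1.07. Of 25 neuroblast genes, 3 fell, also adjusted over the list alone: dpn by 1.52 ± 0.41, wor by 1.21 ± 0.31 and ase by 1.07 ± 0.26. Camera gave 0.00812, and adjusted p = 0.543 with an estimated correlation, and the calls of dpn and wor were lost within IRB, at -1.26 and -1.11 (adjusted p = 0.129 and 0.0867). Without the 5 arrays that stand apart dpn differed by -1.31 (adjusted p = 0.0573). Of 31 cell cycle genes, 3 fell adjusted over the list alone and none over all genes, with a median of -0.62. Over all genes, 3 were called lower within IRB and 3 with a site term from WT alone. Camera gave 6.56e-07, and adjusted p = 0.543 with an estimated correlation. Rbf2, a member of the dREAM complex, fell by 1.87 ± 0.46. l(3)mbt differed by 0.34 ± 0.52, adjusted p = 0.873.

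The ts1 brains at 29 °C were set against those at 17 °C, while no WT array was assigned to a temperature. Several germline genes were higher at 29 °C. cona rose by 8.58 ± 0.24 (SE), adjusted p = 3.11e-19 (limma, Benjamini-Hochberg), krimp by 7.05 ± 0.29, dhd by 6.24 ± 0.54, Pxt by 6.16 ± 0.62 and Muc14A by 5.60 ± 0.34. piwi rose by 4.76 ± 0.87, and within EMBL by 6.31, AGO3 by 4.53 ± 0.66 and zpg by 4.23 ± 0.86. Within EMBL Pxt differed by 5.54, AGO3 by 5.29 and zpg by 5.26. The dopamine transporter gene DAT fell by 2.49 ± 0.46, betaTub97EF by 2.14 ± 0.42 and dac by 2.13 ± 0.53. Without the 5 arrays that stand apart betaTub97EF and dac differed by -1.69 and -1.83 and were not called (adjusted p = 0.0682 and 0.157). limma called 94 genes, 70 higher and 24 lower at 29 °C, and 317 within EMBL, 212 higher and 105 lower. Among piRNA genes, 5 of 28 rose (9 adjusted over the list alone), with a camera result of 2.01e-16 and adjusted p = 0.0248 with an estimated correlation. Among germline genes, 3 of 27 rose (10 adjusted over the list alone), with 5.66e-06 and adjusted p = 0.00159 with an estimated correlation. The glial list was lower, with 3 of 23 genes falling adjusted over the list alone, at 9.63e-05 and adjusted p = 0.0248 with an estimated correlation. l(3)mbt differed by -0.04 ± 0.52, adjusted p = 1.

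Within E2, several of the same genes were higher at 29 °C. Muc14A rose by 9.36 ± 0.36 (SE), adjusted p = 2.92e-16 (limma, Benjamini-Hochberg), Kots by 8.99 ± 0.39, krimp by 7.08 ± 0.31 and cona by 6.94 ± 0.26. BBS8, a gene of cilium assembly, rose by 6.36 ± 0.66, stil by 5.99 ± 0.63, bgcn by 5.94 ± 0.74 and piwi by 3.78 ± 0.93. Among the genes that fell were the salivary glue genes Sgs3, by 7.38 ± 1.81, and Sgs4 by 5.98 ± 1.57, the fat body genes Lsp2 by 6.39 ± 1.58 and Fbp1 by 5.31 ± 1.20, and the pupal cuticle gene Pcp by 5.38 ± 0.94. limma called 459 genes, 228 higher and 231 lower at 29 °C, all on IRB arrays. Of 28 piRNA genes, 9 rose (11 adjusted over the list alone), with a camera result of 8.35e-12 and adjusted p = 0.0812 with an estimated correlation. Of 27 germline genes, 6 rose (8 adjusted over the list alone), with 8.87e-06 and adjusted p = 0.0023 with an estimated correlation. Of 19 meiosis genes, 6 rose (6 higher and 1 lower adjusted over the list alone), with 8.87e-06 and adjusted p = 0.0812 with an estimated correlation. l(3)mbt differed by 0.20 ± 0.55, adjusted p = 0.868.

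The test of whether temperature acted differently on both alleles called 28 genes with limma, 15 with a positive and 13 with a negative value of the ts1 change minus the E2 change. Obp99b had a difference of 9.82 ± 2.02 (SE), adjusted p = 0.0243, and 8.46 with a site term from WT alone. Its group means were 6.23 and 6.76 in ts1 at 17 °C and 29 °C, and 12.71 and 4.78 in E2. Drsl5 had 6.08 ± 1.34 and cona 1.64 ± 0.35. Without the 5 arrays that stand apart Obp99b had 8.55 and Drsl5 4.66, and neither was called (adjusted p = 0.0766 and 0.168). The P450 gene Cyp12a4 had -6.46 ± 1.40, the metabolic enzyme gene Gcat -6.06 ± 1.28 and stil -4.51 ± 0.86. No piRNA gene was called, with 583 genes of all tested at an unadjusted p under 0.05. Both alleles were run at different sites at 17 °C, so no value within a site can be had. l(3)mbt had -0.24 ± 0.76, adjusted p = 0.963.

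**Figure D3:**
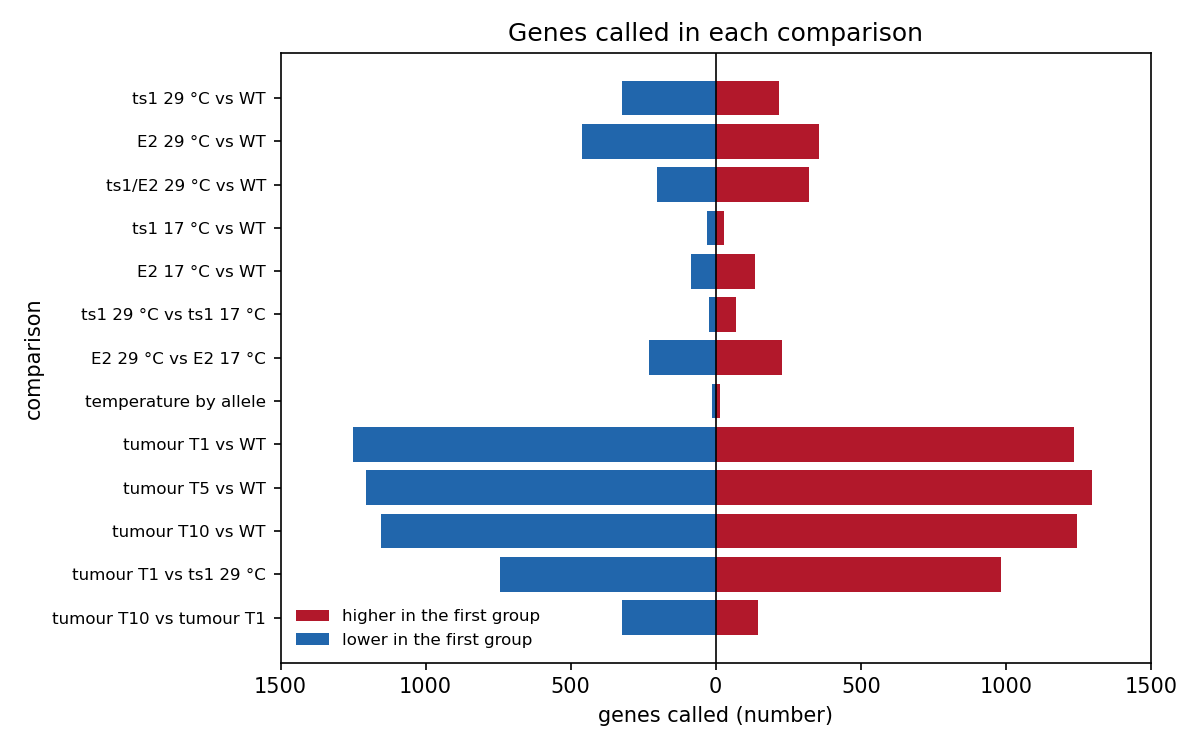
Number of genes called higher and lower by limma in each comparison. The tumour comparisons with WT held 2401 to 2501 genes, and ts1 at 17 °C held 57.

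The tumours, grown on in adult hosts, were each set against WT. In round-1 tumours, cona rose to 13.16 ± 0.02 (SD, n = 3) from 2.90 ± 0.16 (SD, n = 6) in WT, adjusted p = 2.01e-21 (limma, Benjamini-Hochberg), and Kots rose by 10.07 ± 0.37 (SE). krimp rose by 8.58 ± 0.29, aub, a cytoplasmic Argonaute of the germ line, by 6.39 ± 0.87, AGO3 by 7.03 ± 0.66 and piwi by 7.09 ± 0.87, with 5.54 within IRB. gnu rose by 9.11 ± 1.13, nanos, the translational repressor of germ cells, by 7.75 ± 0.76 and the spermatocyte factor topi by 7.84 ± 0.71. The insulin-like peptide gene Ilp5 fell by 9.71 ± 1.03. Within IRB AGO3 differed by 6.27, gnu by 8.42, nanos by 6.58 and Ilp5 by -10.93. Of 28 piRNA genes, 20 rose (20 adjusted over the list alone), with a camera result of 7.65e-11 and adjusted p = 0.0635 with an estimated correlation. Of 27 germline genes, 14 rose (15 adjusted over the list alone), at 6.08e-05 and adjusted p = 0.00356 with an estimated correlation. Of 19 meiosis genes, 8 rose and 1 fell (the same counts adjusted over the list alone), at 0.000476 and adjusted p = 0.119 with an estimated correlation.

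Many glial and neuronal genes fell in round-1 tumours. Of 23 glial genes, 14 fell (14 adjusted over the list alone), among them wrapper, a gene of cortex glia, by 7.24 ± 0.41 and the astrocyte gene alrm by 6.23 ± 0.72. Camera gave 2.86e-07, and adjusted p = 0.00356 with an estimated correlation. Of 23 neuronal genes, 14 fell (17 adjusted over the list alone), Syn by 5.07 ± 0.40 and Snap25 by 4.08 ± 0.41 among them, at 9.04e-07 and adjusted p = 0.0898 with an estimated correlation. Of 16 optic lobe genes, 9 fell and 1 rose (the same counts adjusted over the list alone), Optix falling by 5.86 ± 0.43, at 0.00156 and adjusted p = 0.0242 with an estimated correlation. Of 25 neuroblast genes, 3 fell and 2 rose (the same counts adjusted over the list alone), with a median of 0.08 and a mean of -0.12. The temporal factor Imp rose by 2.21 ± 0.41, while erm fell by 3.18 ± 0.67 and pros, which ends neuroblast divisions, by 1.68 ± 0.23. The polarity gene crb rose by 3.80 ± 0.41 and fj, a target of the Hippo pathway, by 3.97 ± 0.95. Of 14 Hippo genes 7 rose (7 adjusted over the list alone), and camera gave an adjusted p of 0.0721.

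Some marker genes of adult host tissues rose in round 1. The yolk protein genes Yp1, Yp2 and Yp3, made by adult female fat body and ovary, rose by 7.24 ± 0.74, 5.95 ± 0.76 and 4.41 ± 0.82 over WT. Of 10 yolk and adult fat body genes, 6 rose and 1 fell (6 and 2 adjusted over the list alone), and camera gave an adjusted p of 0.0531. The muscle gene Mlp60A rose by 4.77 ± 0.41, with 4 of 17 muscle genes higher and 2 lower (the same counts adjusted over the list alone), and the blood cell genes NimC1 and Hml by 4.37 ± 0.80 and 4.14 ± 0.76, with 6 of 17 hemocyte genes higher and 1 lower (the same counts adjusted over the list alone). Camera gave 0.161 for muscle and 0.0905 for hemocytes. Of 9 immune genes, 8 rose (8 adjusted over the list alone), the immune-induced peptide gene BomS2 by 7.06 ± 0.93. Camera gave 0.000476, and adjusted p = 0.0526 with an estimated correlation. In total, 2483 genes were called in round 1 against WT, 1234 higher and 1249 lower, and 2089 within IRB. l(3)mbt rose by 1.60 ± 0.52 (adjusted p = 0.0152), a call lost within IRB, where the difference was 1.27 (adjusted p = 0.119).

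In round-5 tumours cona rose by 10.31 ± 0.24 (SE), adjusted p = 1.59e-21 (limma, Benjamini-Hochberg), Pxt by 10.09 ± 0.62 (10.72 within IRB) and krimp by 8.72 ± 0.29. The neuronal enzyme gene Gad1, which makes GABA, fell by 8.64 ± 0.55 to 1.97 ± 0.36 (SD, n = 3), the adhesion gene Ama by 9.85 ± 0.39 and alrm by 9.61 ± 0.72. Syp, the temporal factor opposed to Imp, fell by 2.63 ± 0.54, and Imp rose by 2.61 ± 0.41. The JAK-STAT ligand gene upd1 rose by 4.55 ± 0.84 and the stress-induced relaxin gene Ilp8 by 4.59 ± 0.74. The antimicrobial peptide gene Mtk rose by 6.28 ± 1.04 and the chorion gene Cp15 by 4.26 ± 0.51. Yp2 averaged 2.36 and was not called. limma called 2501 genes, 1297 higher and 1204 lower, and 2067 within IRB. The piRNA list had 21 of 28 genes higher (22 adjusted over the list alone), at 4.82e-10 and adjusted p = 0.0663 with an estimated correlation. The germline list had 13 of 27 genes higher and 1 lower (the same counts adjusted over the list alone), at 0.000776 and adjusted p = 0.0123 with an estimated correlation. Of 23 neuronal genes, 16 fell (17 adjusted over the list alone), at 1.28e-09 and adjusted p = 0.0438 with an estimated correlation. Of 23 glial genes, 15 fell (15 adjusted over the list alone), at 1.04e-09 and adjusted p = 0.000559 with an estimated correlation. l(3)mbt rose by 1.79 ± 0.52 (adjusted p = 0.00727), with 1.45 within IRB (adjusted p = 0.0746).

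In round-10 tumours cona rose by 10.23 ± 0.24 (SE), adjusted p = 1.93e-21 (limma, Benjamini-Hochberg), krimp by 8.68 ± 0.29 and fs(1)Yb by 6.71 ± 0.81 (5.98 within IRB). eya, a retinal determination gene of the optic lobe, fell by 6.34 ± 0.41, wrapper by 8.78 ± 0.41 and Snap25 by 6.34 ± 0.41. crb rose by 4.53 ± 0.41 and ds, a cadherin of the Hippo pathway, by 2.92 ± 0.54. Mtk rose by 7.28 ± 1.04 to 9.92 ± 0.38 (SD, n = 3) and Cp15 by 5.24 ± 0.51. limma called 2401 genes, 1247 higher and 1154 lower, and 2012 within IRB. In the piRNA list 19 of 28 genes rose (20 adjusted over the list alone), at 8.21e-09 and adjusted p = 0.0889 with an estimated correlation. In the germline list 12 of 27 genes rose (12 adjusted over the list alone), at 0.00475 and adjusted p = 0.0348 with an estimated correlation. Of 23 neuronal genes, 17 fell (17 adjusted over the list alone), at 9.29e-10 and adjusted p = 0.0348 with an estimated correlation. Of 16 optic lobe genes, 12 fell and 1 rose (the same counts adjusted over the list alone), at 6.49e-07 and adjusted p = 0.00106 with an estimated correlation. Of 14 Hippo genes, 7 rose (7 adjusted over the list alone), at 0.0107 and adjusted p = 0.165 with an estimated correlation. The yolk and adult fat body list had a median of 1.06 and a mean of -0.45, with 4 genes higher and 3 lower (the same counts adjusted over the list alone), and camera gave an adjusted p of 0.779. l(3)mbt rose by 1.91 ± 0.52 (adjusted p = 0.00441), with 1.58 within IRB (adjusted p = 0.0541).

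In the same comparison of round 10 with WT, both chorion genes called, Cp15 and Cp18, were higher, 2 of 4 tested (2 adjusted over the list alone), and all 3 larval fat body genes were lower (3 adjusted over the list alone), with Lsp2 falling by 6.42 ± 1.48. Within IRB Lsp2 differed by -7.29, ImpE1 by -2.50 and Eip93F by -2.41. Of 9 immune genes, 6 rose (7 adjusted over the list alone), DptB by 5.67 ± 0.98 among them, at 0.00099 and adjusted p = 0.0592 with an estimated correlation. Of 31 cell cycle genes, 7 rose and 1 fell (the same counts adjusted over the list alone), the centromere gene cid rising by 2.36 ± 0.61 and Incenp by 1.65 ± 0.35, at 0.0107 and adjusted p = 0.718 with an estimated correlation. Of 10 eye and imaginal disc genes, 5 fell and 1 rose (the same counts adjusted over the list alone), with ct falling by 3.47 ± 0.53, at 0.049 and adjusted p = 0.254 with an estimated correlation. Of 21 ecdysone response genes, 5 fell and 1 rose (the same counts adjusted over the list alone), ImpE1 falling by 3.42 ± 0.80 and Eip93F by 3.21 ± 0.63, and camera gave 0.0538. JNK and JAK-STAT genes had 5 higher, upd1 by 4.52 ± 0.84 among them, and 3 lower of 15 (the same counts adjusted over the list alone), at 0.826. Heat shock proteins had 1 of 11 higher, Hsp68 by 2.55 ± 0.62, at 0.902, and l(3)mbt complexes 1 of 21 higher, at 0.949, each also adjusted over the list alone. Tracheal and cuticle genes had 1 higher and 3 lower of 9 (1 and 4 adjusted over the list alone), at 0.406. No gene of glycolysis (9 tested, camera 0.368) or oxidative phosphorylation (17 tested, camera 0.534) was called by limma, nor was the gene tested for sex composition, with a difference of 0.51.

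**Figure D4:**
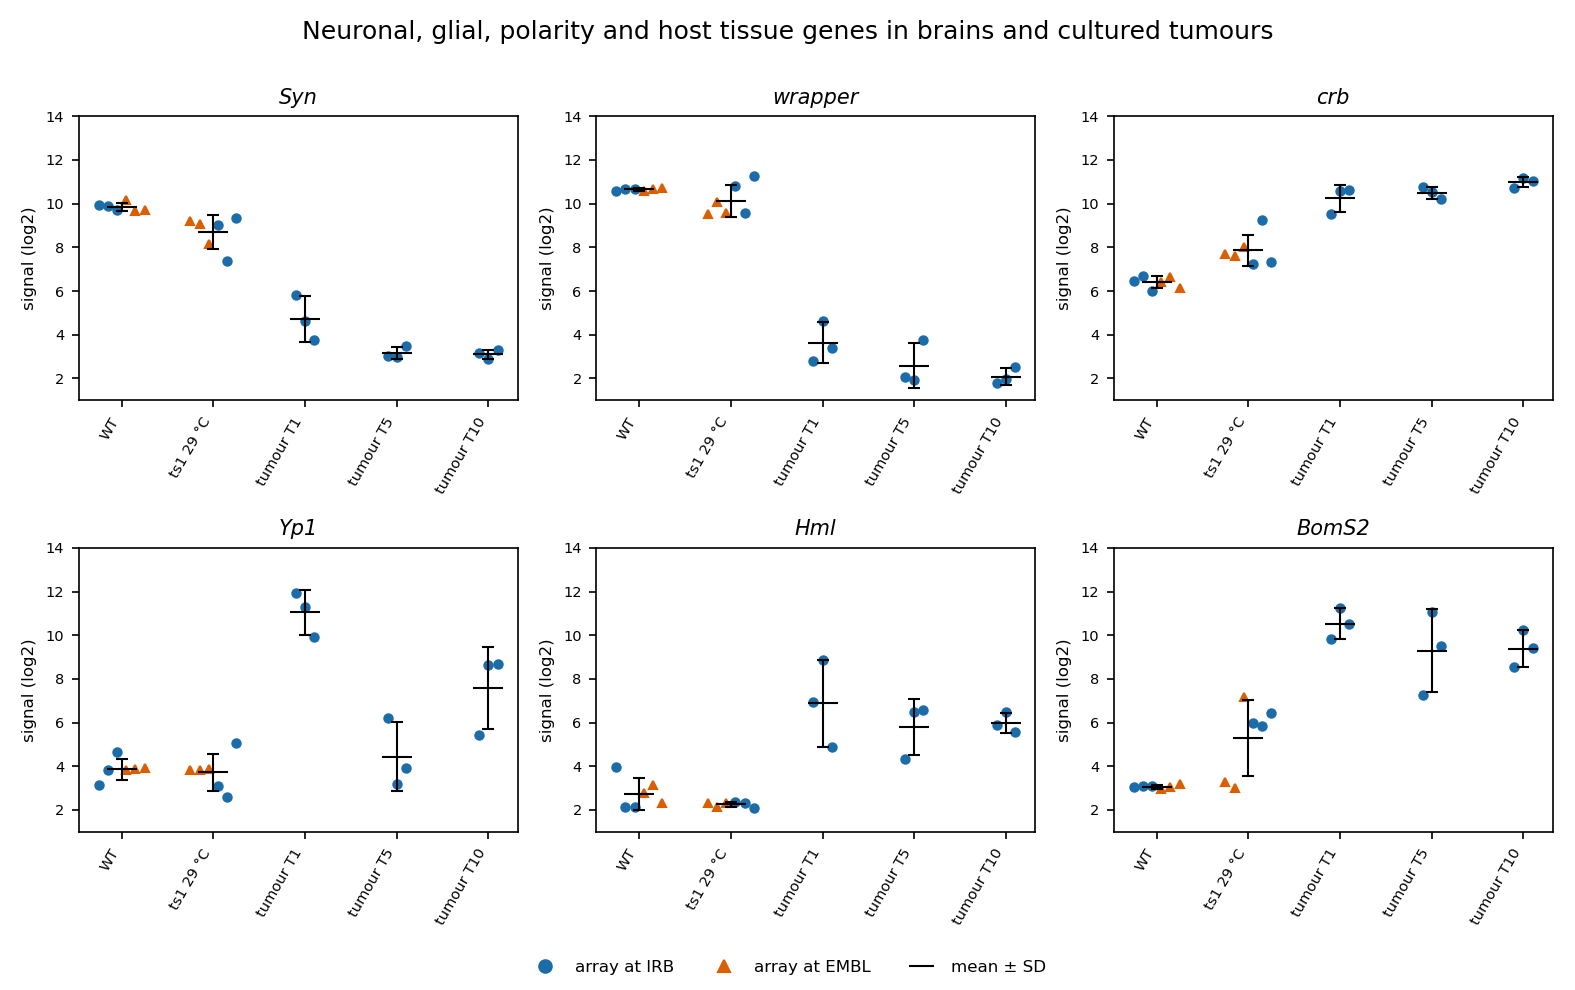
Log2 expression of marker genes on each array in WT, ts1 brains at 29 °C and tumours of each round, with group means as lines. Yp1 averaged 11.05 in round 1 and 7.58 in round 10, and Syn 9.84 in WT and 3.11 in round 10.

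Round-1 tumours were set against the ts1 brains at 29 °C. The P450 genes Cyp4p2 and Cyp4p1 rose by 9.84 ± 0.14 (SE), adjusted p = 9.26e-27 (limma, Benjamini-Hochberg), and by 8.30 ± 0.23. The mucin-like genes Muc11A and Mur18B rose by 8.40 ± 0.87 and 8.33 ± 0.53, and the maltase gene Mal-A1 by 7.81 ± 0.52. Some germline genes rose further, stil by 6.80 ± 0.59, nanos by 5.38 ± 0.76 (6.54 within IRB) and piwi by 3.76 ± 0.87, with 5.31 within IRB. zyd, an ion exchanger gene of cortex glia, fell by 6.90 ± 0.72, wrapper by 6.72 ± 0.41 and Optix by 4.53 ± 0.43. Yp1 rose by 7.40 ± 0.74, Mlp60A by 4.72 ± 0.41 and Hml by 4.62 ± 0.76. limma called 1727 genes, 983 higher and 744 lower, and 1958 within IRB. Of 28 piRNA genes, 15 rose (17 adjusted over the list alone), at 1.74e-05 and adjusted p = 0.237 with an estimated correlation. Of 27 germline genes, 8 rose (8 adjusted over the list alone), at 0.00448 and adjusted p = 0.0386 with an estimated correlation. Of 23 glial genes, 11 fell (11 adjusted over the list alone), at 3.73e-06 and adjusted p = 0.0155 with an estimated correlation. Of 9 immune genes, 7 rose (8 adjusted over the list alone), at 0.00031 and adjusted p = 0.0386 with an estimated correlation. Yolk and adult fat body genes had 5 higher and 1 lower (the same counts adjusted over the list alone), at 0.0169 and adjusted p = 0.102 with an estimated correlation. l(3)mbt differed by 1.21 ± 0.52, adjusted p = 0.0841.

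Round-10 tumours were set against round-1 tumours. eya fell by 7.95 ± 0.43 (SE), from 11.03 ± 0.48 to 3.09 ± 0.25 (SD, n = 3 each), adjusted p = 1.51e-12 (limma, Benjamini-Hochberg), ey by 4.30 ± 0.42 and so by 3.07 ± 0.67. Mur18B fell by 8.20 ± 0.56 and the phosphatase gene Alp2 fell by 6.50 ± 0.62. Of 10 yolk and adult fat body genes, 4 fell (7 adjusted over the list alone), Yp1 by 3.47 ± 0.80, at 1.15e-05 and adjusted p = 0.00554 with an estimated correlation. Of 17 muscle genes, 2 fell (2 adjusted over the list alone), Mlp60A by 4.23 ± 0.44, at 1.15e-05 and adjusted p = 0.0842 with an estimated correlation. Of 27 germline genes, 4 fell (4 adjusted over the list alone), zpg by 4.68 ± 0.92, otu by 3.60 ± 0.95 and exu by 3.43 ± 0.70, at 0.0235 and adjusted p = 0.0842 with an estimated correlation. Of 23 neuronal genes, 8 fell (8 adjusted over the list alone), Gad1 by 4.86 ± 0.58, at 1.15e-05 and adjusted p = 0.17 with an estimated correlation. Of 16 optic lobe genes, 4 fell (4 adjusted over the list alone), at 0.000158 and adjusted p = 0.0072 with an estimated correlation. Esp rose by 7.55 ± 0.45, the ABC transporter gene E23 by 5.12 ± 0.95, the receptor gene mthl10 by 5.10 ± 0.57 and dpn by 2.25 ± 0.44. limma called 467 genes, 145 higher and 322 lower in round 10, and 419 within IRB. l(3)mbt differed by 0.31 ± 0.55, adjusted p = 0.951.

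Genes called higher than WT in all 3 brain groups at 29 °C and all 3 tumour rounds numbered 131, and genes called lower in all 6 numbered 47. Among those with a large smallest difference over the 6 comparisons were cona (9.14), Pxt (9.02), Kots (8.88), Zip102B (7.21), krimp (6.77), dhd (6.35), Muc14A (5.48), corolla (4.95) and TrxT (4.50). In WT these 9 genes averaged 3.43 or lower, near background, so the sizes of their differences and their order are not exact. The piRNA list held 12 of the 131 genes (Fisher's exact test, adjusted p = 9.27e-14), the germline list 6 (adjusted p = 3.99e-05) and the meiosis list 5 (adjusted p = 7.52e-05). Fisher's test takes genes as independent. Camera estimated a correlation of 0.29 within the piRNA list, 0.014 within the germline list and 0.142 within the meiosis list. These p-values can therefore overstate the evidence. The 6 comparisons share the WT arrays. In 100 simulations of unchanged groups against these arrays the highest number shared was 0, and independent lists of the same sizes would share 0.00129 genes. Both are low by design, since the simulated groups held no difference and the real groups are related. The 3 tumour rounds come from ts1 brains, and ts1/E2 carries the ts1 allele. Neither value tells how many genes related groups would share. With WT parted 3 and 3 between the comparisons the number shared lay between 75 and 101 for the higher genes and between 17 and 36 for the lower. Within IRB 68 genes were shared.

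Over all comparisons, camera called 84 of 286 list tests at its preset correlation and 28 with an estimated correlation.

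**Figure D5:**
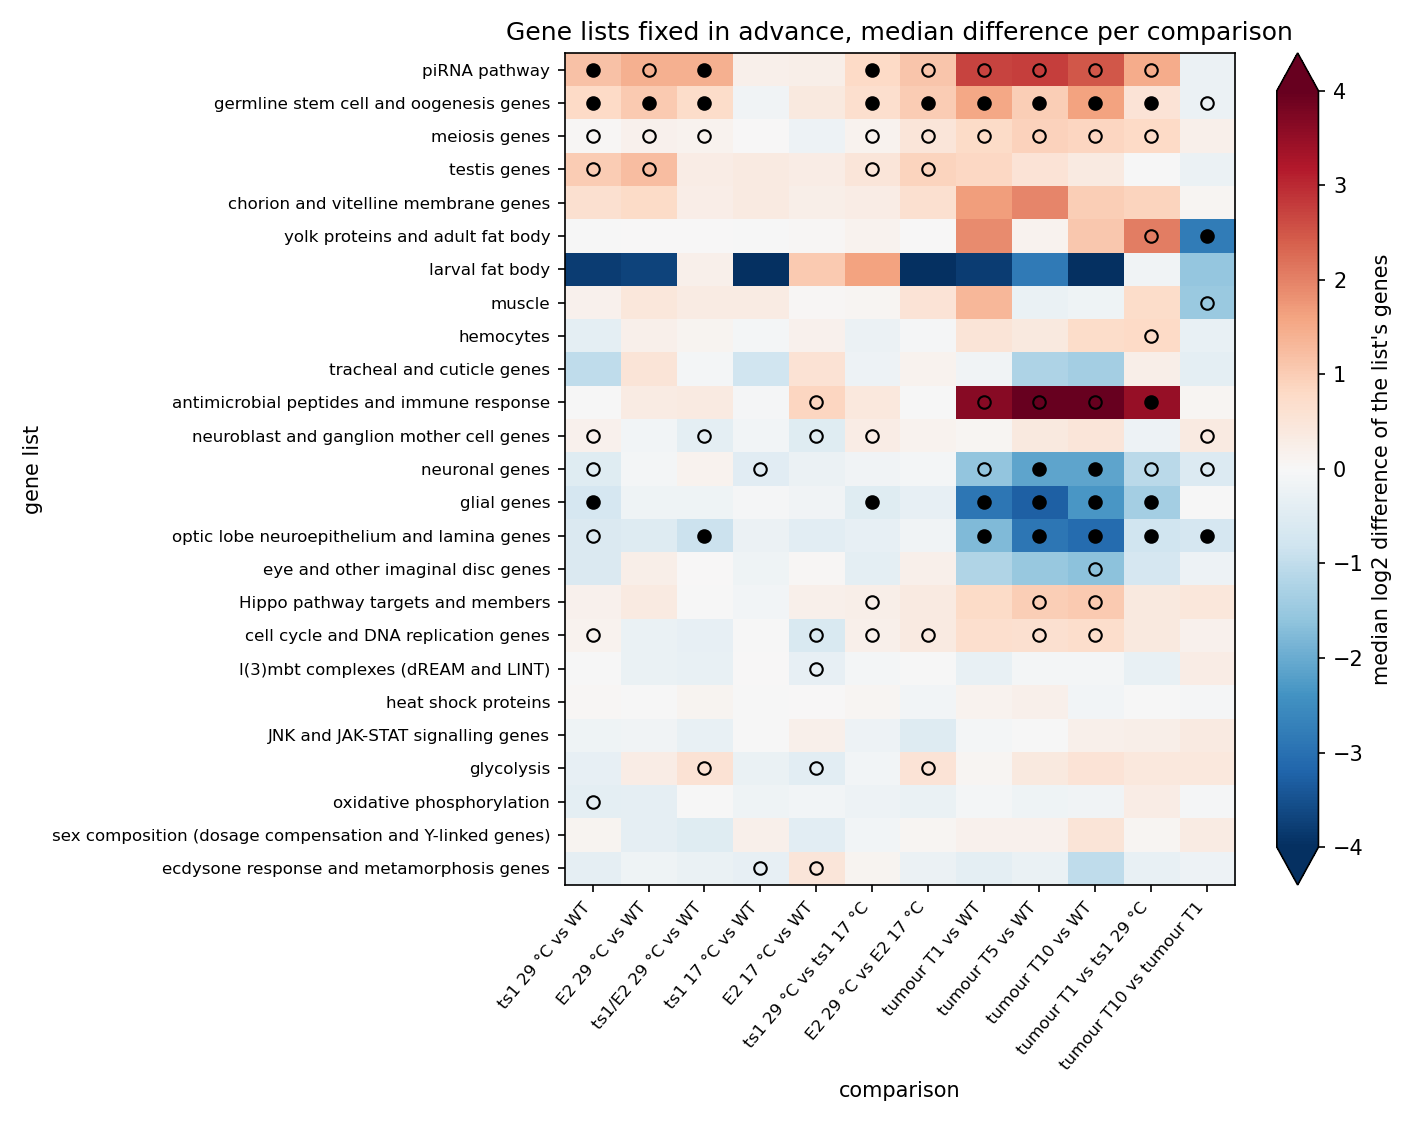
Median log2 difference (colour) of each gene list in each comparison, with a filled dot for a camera result below an adjusted p of 0.05 that also held with an estimated correlation and an open dot for one that did not. The piRNA list had a median of 1.17 in ts1 brains at 29 °C and 2.69 in round-1 tumours.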

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

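The tests of the site difference, of the E2 array and of host tissue were chosen, and those by splits of the samples were written down, only after the results were seen.

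In ts1 brains at 29 °C, 1566 genes were called between the IRB and EMBL arrays, and 304 with the error of WT counted in, with piwi lower at IRB by -6.19 and krimp differing by 0.00. If arrays that stand apart made the difference, it should vanish without replicate 3, with weak 5' signal, and replicate 6, with a median correlation of 0.81, but 1261 of the 1566 genes kept their direction and a difference of 1 or more, which argues against these arrays as the whole cause, although only 720 genes were called without them. If the IRB arrays held WT or 17 °C ts1 brains under a wrong label, few genes should differ from WT at IRB, but 508 did, against 68 between ts1 at 17 °C and WT at EMBL. This argues against WT under a wrong label. For 17 °C ts1 brains the counts come from unlike fits, since none was run at IRB, where E2 brains at 17 °C gave 252. Within IRB cona lay 9.23 and krimp 7.01 above WT, while in ts1 brains at 17 °C they averaged 3.42 and 2.69. Other labels were not tested. Of 105 genes near background in WT and lower at IRB, 95 came within 1 of the EMBL level in another IRB group, but those groups can express the genes more than ts1 brains do. For these and the other 1461 genes an offset left by centring the sites on WT cannot be told apart from a difference between the brains, because WT is equal at both sites by construction, and no biological explanation was tested. Tektin-C, at background in mutant brains, followed the site. Within EMBL it differed from WT by -7.10 in ts1 at 29 °C and -7.09 at 17 °C. Within IRB it differed by -9.40 in ts1 and E2 at 29 °C and -9.385 in E2 at 17 °C. An offset would give such values, but this is 1 gene picked after they were seen.

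Among genes called lower in E2 brains at 29 °C, replicate 1 lay below replicates 2 and 3 by a median of -2.28, against -0.43 for genes not called. These genes were chosen with replicate 1 in the mean, so by this value weak 5' signal on that array and a lower level in the group cannot be told apart. Of the 462 genes, 82 were also called lower in a fit without replicate 1, which argues against that array as the whole cause, while the other 380 were not called lower. In the mean of replicates 2 and 3, 189 of the 462 genes lay at least 1 below WT, a share that leaves open how many of the lower calls come from the allele. Of the 355 genes called higher, 318 were higher in replicates 2 and 3 as well.

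Some germline and adult tissue genes were higher in tumours, which grew inside adult flies. Host tissue carried along would raise yolk and adult fat body genes, and 6 of 10 were called higher in round 1, but transcription in the tumour itself cannot be told apart, since no array held host tissue alone. Of the 37 piRNA and germline genes called higher in a tumour round, 25 were also higher in a 29 °C larval group that had no host, which argues against host tissue as their whole source. The other 12 genes, among them zuc, qin, rhi, otu and orb, were called in tumours alone, and for these host tissue and tumour cells cannot be told apart without arrays of host tissue.

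Regrouping the arrays of each comparison excluded chance for ts1 at 29 °C against WT (1 of 100 splits as large, the real one, with 540 genes against at most 152), round 1 (1 of 84, 2483 against 1159), round 5 (1 of 84, 2501 against 1211) and round 10 (1 of 84, 2401 against 1170). For ts1/E2 the share was 1 of 84 (523 against 424). Its largest other split set the EMBL arrays of WT apart, so the site limits this count, and 401 genes were called within IRB. For the shared genes 1 of 100 regroupings was as large (131 against 0). The regroupings mixed WT, brains and tumours at random, so hardly any gene could be shared. That value cannot decide on chance. For E2 at 29 °C against WT 4 of 84 splits were as large (817 against 2180), a share under 0.05, but 3 of them called more genes than the real one. These, with 2180, 1975 and 1858 genes, joined E2 replicate 1 with EMBL arrays of WT and point to a structure of the samples. The share follows that array, so it cannot decide on chance here. For ts1 at 17 °C against WT (3 of 84, 57 against 306) and E2 at 17 °C against WT (2 of 84, 221 against 323) the share was also under 0.05. The split that set the IRB arrays of WT apart was larger than the real one, so these counts follow the site and cannot decide either. Within a site 68 and 252 genes were called. Round 1 against ts1 brains at 29 °C had 2 of 84 splits as large (1727 against 1916). Its larger split set the IRB ts1 brains apart, so the same limit holds, and 1958 genes were called within IRB.

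Chance was not excluded for ts1 at 29 °C against 17 °C (13 of 84 splits as large, 94 against 300), where splits by site called 172 and 216 and the arrays within EMBL 317, nor for temperature by allele (11 of 100, 28 against 1621), where splits calling many times more genes point to a structure of the samples. E2 at 29 °C against 17 °C had 2 of 10 splits as large (459 against 509) and round 10 against round 1 had 1 of 10 (467 against 32), too few splits to judge.

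Temperature by allele held 28 genes. The site difference of ts1 brains, set against that of WT, which is 0 by the centring, was called in 304 genes, 90 higher and 214 lower at IRB. Dixon's test at 1 in 20 was run on 238 groups of values and marked 21, while about 1 in 20 groups is expected to be marked by chance. In WT these were Ilp8 at 2.92 on replicate 1, otu at 3.86 on replicate 3, Muc11A at 2.84 on replicate 4 and Zip102B at 3.13 on replicate 5. In ts1 brains at 29 °C, replicate 1 stood apart for Mlp60A at 2.83 and Mur18B at 4.42. Replicate 3 stood apart for the 5' minus 3' signal of eIF4a at -4.94 and of actin at -4.78, for Muc11A at 4.20 and for Syp at 10.12. Replicate 5 stood apart for Cp15 at 2.49, Ilp8 at 5.06, ey at 6.90 and mthl10 at 6.20. Replicate 6 stood apart for Drsl5 at 5.55, Mtk at 3.13, Rbf2 at 6.11, Yp3 at 2.59, aub at 3.41, fj at 3.02 and CG13117 at 8.91.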

How the results depend on the processing

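Counts are genes called, and the cause of a change was not tested unless stated. Without a site term E2 at 29 °C against WT had 1422, ts1 at 17 °C 113 and E2 at 17 °C 407. IRB arrays alone gave 485 for E2 at 29 °C, 68 shared genes and -0.29 for l(3)mbt in ts1 at 29 °C against WT. EMBL arrays alone gave 317 for ts1 at 29 °C against 17 °C, with l(3)mbt at 0.30. A filter at 6 turned sv to 0.18 in ts1 at 29 °C against WT. With only the groups compared, E2 at 29 °C had 282, ts1/E2 868, E2 at 17 °C 640, E2 at 29 °C against 17 °C 63, temperature by allele 8 (l(3)mbt 0.10) and round 10 against round 1 90, while l(3)mbt was 0.30 in ts1 at 29 °C against 17 °C. All probe sets gave 87 for ts1 and 342 for E2 at 17 °C, and the mean of probe sets 0.30 for l(3)mbt in ts1 at 29 °C against 17 °C. A common median gave 33 for ts1 at 17 °C, 128 for E2 at 17 °C, 59 for ts1 at 29 °C against 17 °C, 13 for temperature by allele, 80 shared genes and -0.13 for l(3)mbt in E2 at 29 °C against 17 °C. Array weights gave 858 for ts1 at 29 °C, 357 for E2 at 29 °C (CG13117 0.45, Sox14 0.57), 1472 for ts1/E2, 219 for ts1 at 17 °C, 970 for E2 at 17 °C, 509 for ts1 (l(3)mbt 0.26) and 219 for E2 at 29 °C against 17 °C, and 916 for round 10 against round 1. No fold minimum gave 824 for ts1 at 29 °C, by construction. A replicate block gave 101 for ts1 at 17 °C and 182 for ts1 at 29 °C against 17 °C (l(3)mbt 0.30), with l(3)mbt at 0.10 for temperature by allele. Estimated correlation called 28 list tests against 84.

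Of the alternatives chosen after the data were seen, a site term from WT alone gave 98 for ts1 at 17 °C, 353 for E2 at 17 °C and 80 for temperature by allele. Leaving out 3 weak arrays gave 390 for E2 at 29 °C, 348 for E2 at 17 °C, and 41 and 298 for 29 °C against 17 °C in ts1 and E2. Leaving out 5 gave 486, 863, 90 and 468 for E2 at 29 °C, ts1/E2, ts1 at 17 °C and E2 at 17 °C against WT, with l(3)mbt at 0.075 in ts1 at 29 °C against 17 °C. With the site term from WT as well, ts1 at 29 °C had 827, E2 at 29 °C 493, ts1/E2 937, ts1 at 17 °C 138, E2 at 17 °C 560, ts1 at 29 °C against 17 °C 197, temperature by allele 134 and round 10 against round 1 732.

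Leaving out 1 array, E2 at 29 °C against WT ranged from 387 (without E2 replicate 1) to 2069 (without replicate 2), with 1553 without replicate 3. The range was 279 (without E2 17 °C replicate 1) to 1359 (without E2 29 °C replicate 2) for E2 at 29 °C against 17 °C, 129 (without E2 17 °C replicate 1) to 233 for E2 at 17 °C, 21 (without ts1 17 °C replicate 3) to 188 (without replicate 1) for ts1 at 17 °C, and 52 (without ts1 17 °C replicate 2) to 168 (without ts1 29 °C replicate 6) for ts1 at 29 °C against 17 °C. It was 17 (without ts1 17 °C replicate 3) to 51 (without E2 29 °C replicate 2) for temperature by allele, 309 (without round-10 replicate 2) to 480 for round 10 against round 1, and 319 (without ts1/E2 replicate 2) to 502 for ts1/E2. l(3)mbt ranged from -0.28 to 0.17 in ts1 and from -0.29 to 0.92 in E2 at 29 °C against 17 °C, and from -0.96 to 0.25 for temperature by allele.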

Other observations

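A second probe set of l(3)mbt was left out of the tests because it is weaker. Like the first, it averaged above WT in the tumours and in every brain group at 29 °C, by larger amounts. It averaged 2.92 ± 0.05 (SD, n = 6) in WT and 2.93 in ts1 brains at 17 °C, 4.21 ± 1.43 in ts1 brains at 29 °C, 4.49 ± 1.11 and 6.02 ± 0.57 in E2 brains at 17 °C and 29 °C, 5.17 ± 1.22 in ts1/E2 brains, and 6.25 ± 0.65, 5.76 ± 0.40 and 6.78 ± 0.29 in tumours of rounds 1, 5 and 10. The value in round 10 lay 3.86 above WT, which is near background, so that size is not exact. It was examined after the values were seen and was not tested with limma.

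Tektin-C averaged 3.34 or lower in every mutant brain group, and Zip102B 9.46 or higher in every mutant and tumour group. In round-5 tumours Tektin-C lay at 9.25 on replicate 1 and at 1.05 and 1.03 on the others. In ts1 brains at 17 °C Tektin-C stood at 3.34 ± 0.01 (SD, n = 3) against 10.43 ± 0.03 (SD, n = 6) in WT, and Zip102B at 9.46 ± 0.18 against 2.93 ± 0.11. cona, by contrast, stood at 3.42 ± 0.03 in ts1 and 5.57 ± 0.25 in E2 at 17 °C. These genes were set side by side after their values were seen. A difference between the w1118 background and that of the mutant stocks was not tested.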
